A study of Homo sapiens with 3 samples.

How the data were processed

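H3K27ac ChIP-seq was carried out on HEC-1-B cells of 3 genotypes, with 1 library each, and no library of unedited cells was used here. Per the submitters' processing notes, reads were aligned with Bowtie 1 to hg19 (GRCh37). Per the file contents, peaks were called for each library separately with MACS, since the deposited peak names carry that name. The MACS version and options, the control library, duplicate handling and read depth are not given in the sources used here. Each deposited file lists chromosome, start, end, name and a score in 5 columns. From its values, which run from 50 to 3100 in every list, the score deposited by the authors was read as the negative log10 of the caller's p-value times 10. Such a score grows with depth, so it was used only to rank and describe peaks within one list. Scores printed side by side for several lists are not comparable between them. The inserted mouse sequence is not part of hg19, so no listed peak can be placed on it. Whether reads from it aligned elsewhere in hg19 was not examined. Coordinates are printed 1-based.

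Peaks were used as deposited. A peak counted as shared when it overlapped a peak of the other list by at least 1 bp (bedtools 2.31.1, Python 3.11.15, pandas 2.3.3, numpy 2.4.6). Shares carry exact Clopper-Pearson 95% intervals (scipy 1.17.1), which cover the sampling of peaks and not the spread between cultures or libraries. Intervals of ratios of chromosome shares are 95% intervals on the log scale from the peak counts and cover counting error only. With 1 library per genotype no test between genotypes was possible. Plots were drawn with matplotlib 3.10.9. The overlap functions were tested on simulated lists made from the 29341 mE1 peaks with known shared fractions, and the largest departure from the known share was 0.16 percentage points. The 3 pairs of genotypes were compared in both directions, by share, Jaccard index, 10% steps of score, width, promoter peaks, chromosomes and windows of 5 Mb with at least 20 peaks.

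An hg19 annotation was not used here. Gene starts in hg19 came from background knowledge, and a promoter peak is one within 2 kb of such a start. Of the 163 examined genes, 36 starts were written down before the data were examined and 127 after, for further members of gene lists fixed earlier. A further 16 starts in and next to the protocadherin region and 28 at leading peaks were added after the peaks had been seen. All 207 starts lie on the chromosome given in the RefSeq gene table of assembly GRCh38.p14, and 0 neighbouring starts were out of the table's order. That table's coordinates were not used. A wrong start can hide a promoter peak, or give a false peak or a false difference between lists. As a control, starts moved by 50 kb in one direction had a peak at 28, 22 and 22 genes in mE1, mE2 and mE1_CBSmutation, and in the other direction at 28, 22 and 19, against 93, 82 and 71 at the starts themselves. The gene lists, 19 lists with 272 genes, were fixed before the data were examined, and 162 of their members had an hg19 start. Protocadherin lists were covered through the region itself.

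The named features followed a rule fixed beforehand: every peak of the protocadherin region; for each pair and direction the 10 highest-ranked peaks without a partner; the 10 highest-ranked peaks shared by all 3; and up to 4 members of each gene list whose pattern differed between genotypes, otherwise the first 2 in the list's order. Weak or less informative members of these sets are given as counts, and ties were broken by position. Of the 60 leading unpartnered peaks, 35 had a gene start from background knowledge within 2 kb. The others may lie at promoters whose starts were not written down. Genes named beyond this rule were chosen after their values were seen. Some genes that the rule names are not reported here. The bounds of the protocadherin region were set beforehand from background knowledge to span all 3 clusters. For each gene list and direction, the number of members lost was placed among 10000 random draws. Each draw took as many genes as the list had members with a promoter peak in either line. Genes were drawn from the members of any list with such a peak. Peaks like a given peak had a score within 10% and a width within 25% of it.

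Alternatives fixed beforehand were peaks above the median score of each list, lists trimmed to equal length, merging of peaks within 1 kb, reciprocal overlap of 50%, sharing within 1 kb, chromosomes 1 to 22 and X, promoter windows of 500 bp and 5 kb, a protocadherin region extended by 100 kb and windows of 2 Mb. Restrictions to peaks of 2 to 4 kb, and to genes whose peak was at most 4 kb wide, were added after the data were seen.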

Results

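H3K27 acetylation, a histone mark of active promoters and enhancers, was mapped by ChIP-seq in 3 edited derivatives of HEC-1-B, a human endometrial adenocarcinoma cell line. Each derivative carries a mouse enhancer element inserted into the human protocadherin alpha (PCDHA) cluster on chromosome 5. The genotype mE1 carries the HS5-1 element, mE2 carries the HS5-1BL element, and mE1_CBSmutation carries HS5-1 with its CTCF binding sites (CBSs) mutated. HS5-1 is an enhancer of the alpha genes that lies, in the native locus, between the alpha and beta clusters. The exact insertion site of the mouse elements and the meaning of BL are not given in the sources used here. There was 1 library per genotype, so no difference between genotypes has a replicate check and no p-value is given. Unedited cells were not analysed here. The authors' lists held 29341 peaks covering 71.5 Mb in mE1, 29886 peaks covering 76.4 Mb in mE2 and 23172 peaks covering 64.3 Mb in mE1_CBSmutation. Read depth is not given in the sources used here. Coordinates are hg19. A gene missing from a list had no called peak within 2 kb of its start, which is not the same as no acetylation.

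The first question was where the edited region itself carried called peaks. The clustered protocadherin region of chromosome 5, taken from before the alpha cluster to after the gamma cluster, held 12 peaks in mE1, 10 in mE2 and 12 in mE1_CBSmutation. The alpha cluster accounted for 6, 5 and 4 of these, in that order. Among peaks above the median score of each list, the whole region held 9, 5 and 5. At PCDHA6, one of the variable alpha promoters, a peak was called in mE1 (140207292 to 140208628, score 257) and in mE2 (140207359 to 140208109, score 112), and none in mE1_CBSmutation. At PCDHAC1, a peak was called in mE1 (140305428 to 140307081, score 193) and in mE1_CBSmutation (140305554 to 140307150, score 87.9), and none in mE2. PCDHA12 and PCDHAC2 had a peak in all 3 lists. The PCDHA12 peak scored 232 in mE1, 220 in mE2 and 132 in mE1_CBSmutation, and the PCDHAC2 peak scored 356, 472 and 310. By rank, the PCDHA12 peak stood in the top 31.8%, 47.1% and 52.5% of these lists, and the PCDHAC2 peak in the top 15.3%, 19.4% and 11.4%. The scores are the authors' and place a peak only within its own list. Median scores were 149 in mE1, 203 in mE2 and 139 in mE1_CBSmutation.

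Away from the alpha promoters, a peak before PCDHAC1 was called in mE1 (140295545 to 140296837, score 154) and mE2 (140295451 to 140296765, score 158), and none in mE1_CBSmutation. A wider peak after PCDHAC2 was called in all 3 lists, at 140380249 to 140385174 in mE1. In the interval that holds native HS5-1, all 3 lists had the same pair of sites. The site nearer the beta cluster spanned 140421710 to 140423703 in mE1, 140420966 to 140422915 in mE2 and 140421102 to 140423857 in mE1_CBSmutation. It stood in the top 8.72% of the mE1 list by score, the top 9.91% of the mE2 list and the top 0.811% of the mE1_CBSmutation list. The scores there were 429, 628 and 534, in the same order. With 1 library per genotype, these ranks and scores cannot show whether the site differs between genotypes. The other site was called at 140401681 to 140407148 in mE1, 140403588 to 140404159 in mE2 and 140403655 to 140406420 in mE1_CBSmutation. The promoter of TAF7, which encodes a subunit of the general transcription factor TFIID, lies between the beta and gamma clusters and had a peak in all 3 lists. The beta cluster held 1 weak peak per list, and no 2 of them overlapped. The mE2 peak (140466117 to 140466676) and the mE1_CBSmutation peak (140466850 to 140467597) lay within 1 kb of each other, and the mE1 peak (140482678 to 140483199) lay apart. The gamma cluster held 2 peaks in mE1, 1 in mE2 and 4 in mE1_CBSmutation.

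How often a peak of like score and width lacked a partner elsewhere gives a setting for these absences. Such a share holds misses in calling and real differences together. Of 272 other mE1 peaks with a score within 10% and a width within 25% of the PCDHA6 peak, 26 had no overlapping mE1_CBSmutation peak (9.56%, exact 95% interval 6.34 to 13.7). Of 766 mE1 peaks like the PCDHAC1 peak, 101 had no mE2 partner (13.2%, 10.9 to 15.8). Of 705 like the peak before PCDHAC1, 222 had no mE1_CBSmutation partner (31.5%, 28.1 to 35.1). The 5 Mb window of chromosome 5 that starts at 140 Mb and holds the region had 79, 82 and 76 peaks in mE1, mE2 and mE1_CBSmutation, which as shares of each list were 1.02 times the mE1 share in mE2 and 1.22 times in mE1_CBSmutation.

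**Figure D1:**
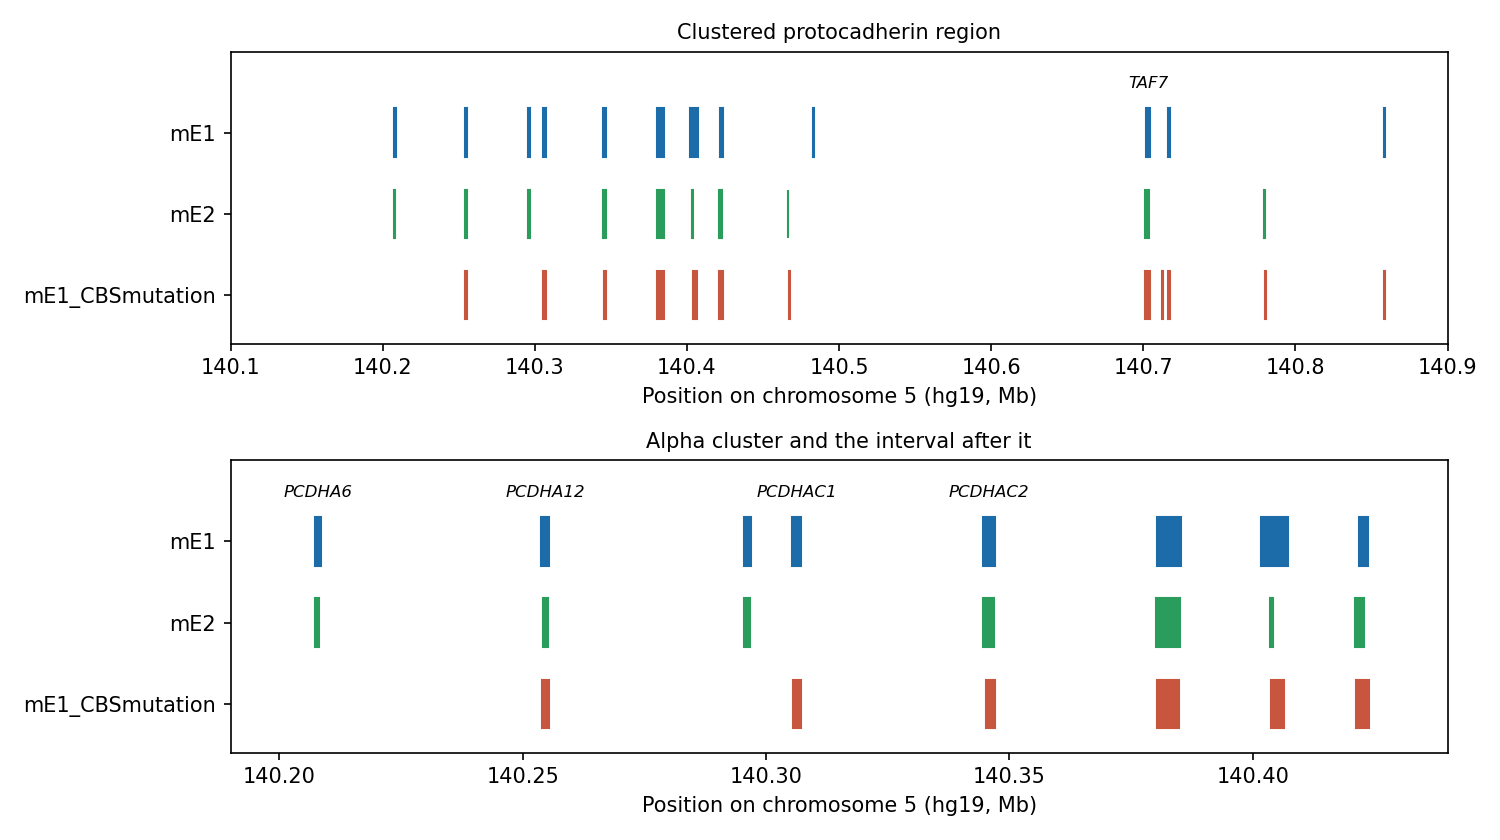
Called H3K27ac peaks along chromosome 5 (hg19, Mb) in the clustered protocadherin region (upper panel) and in the alpha cluster with the interval after it (lower panel), 1 row per genotype, boxes drawn to scale with a thin outline that keeps the narrowest visible. The PCDHA6 peak appears in mE1 and mE2, the PCDHAC1 peak in mE1 and mE1_CBSmutation, and the PCDHA12 and PCDHAC2 peaks in all 3.

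The comparison of mE1 with mE1_CBSmutation asks what differs when the same inserted element lacks its CTCF sites. The highest-ranked peaks found in mE1 alone of the pair lay, among others, at TAOK1 (a protein kinase, chromosome 17, 27716469 to 27719076, score 721), MLST8 (a subunit of the mTOR complexes, score 719), IRF3 (an interferon regulatory transcription factor, score 706), JMJD6 (score 673), CSNK1D (casein kinase 1 delta, score 640), STRN4 and YWHAE. All 10 highest-ranked such peaks stood in the top 3.36% of the mE1 list, and 6 of them were also called in mE2. In the reverse direction the leading peaks lay, among others, at SDC3 (a syndecan, chromosome 1, 31381575 to 31385058, score 551), RAP2B (score 447), GSK3B (glycogen synthase kinase 3 beta, score 409), BZW2 and ZNF395. Of 163 genes examined, 93 had a promoter peak in mE1 and 71 in mE1_CBSmutation. A peak in mE1 and none in mE1_CBSmutation was found at 26, among them CTCF and RAD21, and the reverse at 4, among them KRT7, SOX17 and LGR5.

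Genome-wide, 69.6% of mE1 peaks overlapped an mE1_CBSmutation peak (20431 of 29341, exact 95% interval 69.1 to 70.2), and 87.5% of mE1_CBSmutation peaks overlapped an mE1 peak (87.1 to 88.0). The intervals cover the sampling of peaks only. With both lists trimmed to their highest-scoring peaks at equal length, the share was 79.6% in either direction. The Jaccard index in base pairs was 0.553. The share rose with score: 26.9% of the lowest-scoring 10% of mE1 peaks had an mE1_CBSmutation partner, against 98.4% of the highest-scoring 10%. In the reverse direction these shares were 57.9% and 99.7%. At equal list length the lowest-scoring 10% gave 44.9% for mE1 and 39.1% in reverse, so the order of the lowest shares depends on list length.

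Width went with the presence of a partner as well, in peaks that were not matched by score beyond a cut at the median. Of 972 mE1 peaks over 6 kb, 296 scored above the median, against 8466 of 11380 of 2 to 4 kb. Width was therefore not separated from score. Among mE1 peaks above the median score, 419 of 8466 peaks of 2 to 4 kb (4.95%) lacked an mE1_CBSmutation partner, against 72 of 296 peaks over 6 kb (24.3%). Narrow peaks lacked a partner more often as well, at 20 of 110 up to 1 kb (18.2%) and 466 of 3585 from 1 to 2 kb. Of the 1258 such peaks without a partner, 905 (71.9%) were 4 kb or narrower. Most mE1 peaks above the median score were that narrow: of 14669, 8466 were 2 to 4 kb wide, 3585 were 1 to 2 kb and 110 up to 1 kb. Peaks of 4 kb or narrower were thus a larger share of all these peaks than of those without a partner. Over peaks of any score, 66.5% of those up to 1 kb and 34.7% of those over 6 kb lacked one. The reverse comparison above the median score gave 1.01% at 2 to 4 kb and 9.4% over 6 kb. No list held a peak over 9 kb, the widest being 8664 bp in mE1, 8990 bp in mE2 and 8717 bp in mE1_CBSmutation. Of the 26 genes with a promoter peak in mE1 alone of the pair, 13 had an mE1 peak over 4 kb, against 18 of the 67 with a peak in both. An alternative chosen after the data were seen, which kept only genes whose mE1 peak was at most 4 kb wide, left 13 of the 26. In the reverse direction the same limit on the mE1_CBSmutation peak left 3 of the 4. With lists of equal length the 2 counts were 23 and 6, and above the median score they were 32 and 4.

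**Figure D2:**
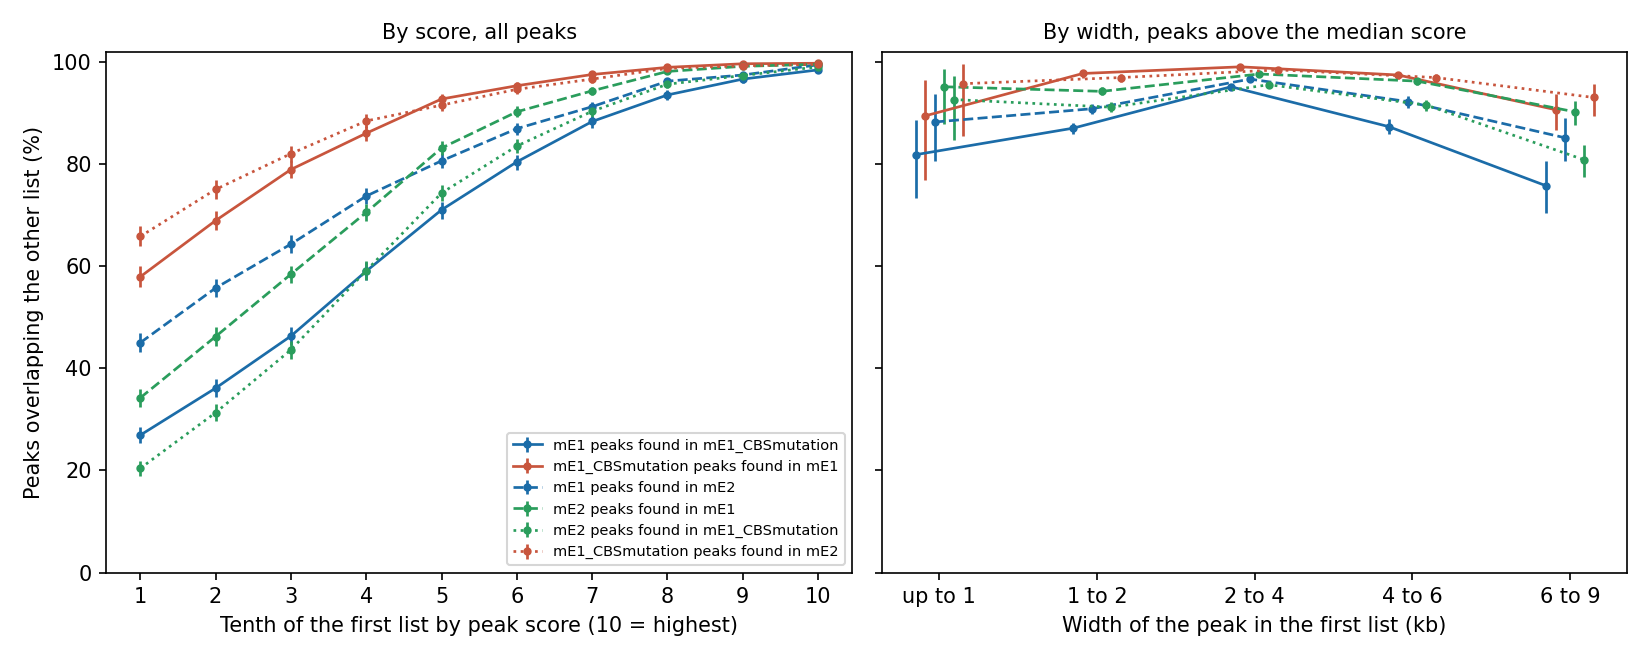
Share of the first list's peaks that overlap the other list (%), by 10% steps of peak score within the first list (left) and by peak width for peaks above the median score (right), with exact 95% intervals as bars, 1 line per ordered pair of lists and points in the right panel shifted sideways for legibility. The share of mE1 peaks found in mE1_CBSmutation rises from 26.9% to 98.4% with score, and in all 6 ordered pairs it is lower for peaks over 6 kb, and for peaks under 2 kb, than for peaks of 2 to 4 kb.

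The comparison of mE1 with mE2 sets the HS5-1 and HS5-1BL insertions side by side. Among those at a named gene, peaks in mE1 without an mE2 partner were led by IRF3, CSNK1D, MRPL12 (a mitochondrial ribosomal protein, score 600), MB21D2, ARHGAP11B and PDCD6IP (an endosomal sorting factor, score 554). IRF3 and CSNK1D had a promoter peak in mE1 and in neither other line. Among those at a named gene, peaks in mE2 without an mE1 partner were led by SDC3 (chromosome 1, 31381613 to 31385145, score 1022), RASSF9 (score 889), TSPAN12 (a tetraspanin, score 761) and BCL6 (a transcriptional repressor, score 743). Each of these was also called in mE1_CBSmutation. Leading peaks without a named gene on chromosome 12 (71555102 to 71559267, score 783) and chromosome 14 (105556149 to 105561539, score 677) were not. Of the examined genes, 17 had a promoter peak in mE1 and none in mE2, and 6 the reverse. With genes whose peak in the first line was at most 4 kb wide, these counts were 7 and 2. Of mE1 peaks, 79.0% overlapped an mE2 peak (78.6 to 79.5), and of mE2 peaks 77.4% overlapped an mE1 peak (76.9 to 77.8). The Jaccard index was 0.557. The shares were 45.0% and 34.2% in the lowest-scoring 10% of each list, and 99.4% and 99.5% in the highest. Among peaks above the median score, 14.9% of mE1 peaks over 6 kb lacked an mE2 partner, against 3.43% of those of 2 to 4 kb.

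The mE2 and mE1_CBSmutation lines differ in the inserted element, and CTCF sites are mutated in mE1_CBSmutation. Whether HS5-1BL holds CTCF sites is not given in the sources used here. Of the 10 leading mE2 peaks without a partner, those at a named gene lay at BAIAP2L2 (chromosome 22, 38505739 to 38509030, score 1145), at MLST8 (score 854) and at SCGB1D2, which encodes a secretoglobin (score 773). All 3 were also called in mE1. The others had no named gene, and one of them, on chromosome 12 (71555102 to 71559267, score 783), was not called in mE1. Of the 10 leading mE1_CBSmutation peaks without an mE2 partner, those at a named gene lay at PDCD6IP (score 489), KBTBD2 (score 482), LIMD1 (a LIM domain protein, score 415), C1GALT1 (a glycosyltransferase, score 377), MB21D2, ARFGEF1 and SACM1L. These 7 were also called in mE1. A peak without a named gene on chromosome 2 (20377259 to 20381367, score 383) was not called in mE1. Of the examined genes, 14 had a promoter peak in mE2 and none in mE1_CBSmutation, and 3 the reverse, among them COL1A2 and STAG1. Restricted to first-line peaks of at most 4 kb, these counts were 4 and 2. With lists of equal length they were 10 and 6. Of mE2 peaks, 69.5% overlapped an mE1_CBSmutation peak (68.9 to 70.0), and 89.1% of mE1_CBSmutation peaks overlapped an mE2 peak (88.7 to 89.5). At equal list length the shares were 81.7% and 81.8%. The Jaccard index was 0.57.

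Over the 3 lists together, 36868 merged regions were covered. All 3 lists shared 18844 of them (51.1%), 4769 were in mE1 alone (12.9%), 5001 in mE2 alone (13.6%) and 1182 in mE1_CBSmutation alone (3.21%). A further 4070 were in mE1 and mE2, 1319 in mE1 and mE1_CBSmutation, and 1683 in mE2 and mE1_CBSmutation. The highest-scoring shared peaks, 121482915 to 121485548 on chromosome 1 and 58776031 to 58780280 on chromosome 6, reached the score limit of 3100 in mE1 and lie next to centromeres.

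The next comparison took genes in groups. Of the 162 members of the gene lists that were examined, 64 had a promoter peak in all 3 lists and 63 in none. Among 21 markers of epithelial and endometrial identity, 10 had a peak in each list and 8 had one in all 3, among them the surface antigen gene EPCAM, the keratin genes KRT8 and KRT18, MUC1, and the transcription factor genes ELF3, FOXA2 and HOXA10. KRT7 and SOX17 had a peak in mE2 and mE1_CBSmutation and none in mE1, and these peaks were weak, at scores of 69.1 and 62.2 for KRT7 and 67.1 and 52.8 for SOX17. KRT19 and HOXA11 had one in mE1 alone. None of 13 blood cell markers, such as GATA1 and TAL1, and none of 7 neuronal markers, such as NEUROD1 and SYP, had a promoter peak in any list. With a promoter window of 5 kb, 2 blood cell markers had a peak in mE1, 1 in mE2 and 1 in mE1_CBSmutation, and still no neuronal marker in any list. Of 12 mesenchymal genes, COL1A1 and ZEB1 had a peak in all 3, COL1A2 in mE1 and mE1_CBSmutation, VIM in mE1 and mE2, and FN1 in mE1 alone. With a window of 500 bp, 3, 2 and 1 mesenchymal genes had a peak in mE1, mE2 and mE1_CBSmutation, and above the median score 2, 2 and 1.

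Among 11 genes of the CTCF and cohesin machinery, 11 had a promoter peak in mE1, 10 in mE2 and 9 in mE1_CBSmutation. CTCF itself and the cohesin subunit gene RAD21 had a peak in mE1 and mE2 and none in mE1_CBSmutation, and STAG1 had one in mE1 and mE1_CBSmutation and none in mE2. The CTCF peak was 4482 bp wide in mE1 (chromosome 16, 67594727 to 67599208, score 307) and 6034 bp wide in mE2. The RAD21 peak was 3573 bp wide in mE1 (chromosome 8, 117884193 to 117887765, score 347) and scored 767 in mE2. The STAG1 peak was 7898 bp wide in mE1. Of random draws of 11 genes, 85.9% lost 2 or more from mE1 to mE1_CBSmutation, where this list lost 2. SMC3, a core cohesin subunit, was called in all 3 with scores of 503, 1030 and 452, in the top 4.33%, 1.0% and 2.23% of the lists.

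Of 16 housekeeping genes, a promoter peak was called at 15 in mE1, 11 in mE2 and 9 in mE1_CBSmutation. GAPDH, RPL13A, YWHAZ and HNRNPA2B1 had one in mE1 alone, and ACTB and HSPA8 in mE1 and mE2. The mE1 peak was 6148 bp wide at ACTB, 6015 bp at GAPDH and 7614 bp at YWHAZ. It was 5293 bp at RPL13A, 7306 bp at HNRNPA2B1 and 3604 bp at HSPA8. Peaks over 6 kb lacked a partner more often than those of 2 to 4 kb. These counts are of called peaks and cannot be read as lost acetylation. Random draws of 15 genes were taken 10000 times from list members with a promoter peak in mE1 or mE1_CBSmutation. Of these, 18.2% lost 6 or more from mE1 to mE1_CBSmutation, where this list lost 6.

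The stress and signalling groups varied. All 9 interferon response genes had a promoter peak in every list, and among peaks above the median score 8 had one in mE1, 5 in mE2 and 3 in mE1_CBSmutation. The peak at ISG15, a ubiquitin-like protein gene, scored 354 in mE1, 142 in mE2 and 98.5 in mE1_CBSmutation. That at IFIT1, an antiviral RNA-binding protein gene, scored 354, 609 and 261. By rank they stood in the top 15.5%, 62.1% and 67.1% of the lists at ISG15, and 15.6%, 10.8% and 18.7% at IFIT1. For the step from mE1 to mE1_CBSmutation, 5.38% of random draws of 9 genes lost as few as this list. Of 11 NF-kB target and chemokine genes, 4 had a peak in mE1, 3 in mE2 and 1 in mE1_CBSmutation: NFKBIA, the inhibitor of NF-kB, in all 3, BIRC3 and TNFAIP3 in mE1 and mE2, and the cytokine gene IL6 in mE1 alone. The mE1 peaks at TNFAIP3, IL6 and BIRC3 were 1574, 2456 and 3454 bp wide. Of the 4 genes with a peak in mE1 or mE1_CBSmutation, 3 had none in mE1_CBSmutation. Of random draws of 4 genes, 5.66% lost as many or more. Above the median score, 3, 1 and 0 of the 11 genes had a peak in mE1, mE2 and mE1_CBSmutation. With a promoter window of 5 kb 5, 5 and 2 had one, so mE1 and mE2 were then equal. Of 9 TGF-beta and YAP target genes, 1 had a peak in mE1, 3 in mE2 and 2 in mE1_CBSmutation. CCN2 was called in all 3, and CCN1 and SMAD7 in mE2 alone. The mE2 peaks at CCN1 and SMAD7 were 5996 and 5429 bp wide. Only 3 members had a peak in mE1 or mE2, and 0.88% of random draws of 3 genes gained 2 or more from mE1 to mE2. With lists of equal length 1 member had a peak in mE1, which was CCN2, and 1 in mE2, which was SMAD7, since the mE2 peaks at CCN1 and CCN2 were among those trimmed. With a promoter window of 5 kb, 3, 5 and 2 members had a peak in mE1, mE2 and mE1_CBSmutation, and above the median score 0, 1 and 0, so the mE1 count depends on the window. In all, 74 such percentiles were computed, and they describe these libraries only.

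In the other groups, promoter peaks in mE1, mE2 and mE1_CBSmutation were called at 8, 7 and 6 of 13 AP-1 and immediate early genes, with FOSL2 in mE2 alone and ATF3 and IER2 in mE1 alone. Of 10 hypoxia and glycolysis genes, 8, 8 and 6 had a peak, with BNIP3 and EGLN3 missing from mE1_CBSmutation. Of 6 p53 targets, 4, 2 and 2 had a peak, with BBC3 and GDF15 in mE1 alone. Of 9 cholesterol synthesis genes, 5, 5 and 4 had one, with IDI1 missing from mE1_CBSmutation. Of 8 Wnt targets, 5, 4 and 4 had one. SP5 and TCF7 were called in mE1 alone, and LGR5, an intestinal stem cell marker, in mE2 and mE1_CBSmutation with peaks of 4541 and 5185 bp. Of 7 unfolded protein response genes, 7, 6 and 5 had a peak, with ATF4 missing from mE1_CBSmutation and DDIT3 in mE1 alone. Of the HOX clusters only HOXA10 and HOXA11 were examined.

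**Figure D3:**
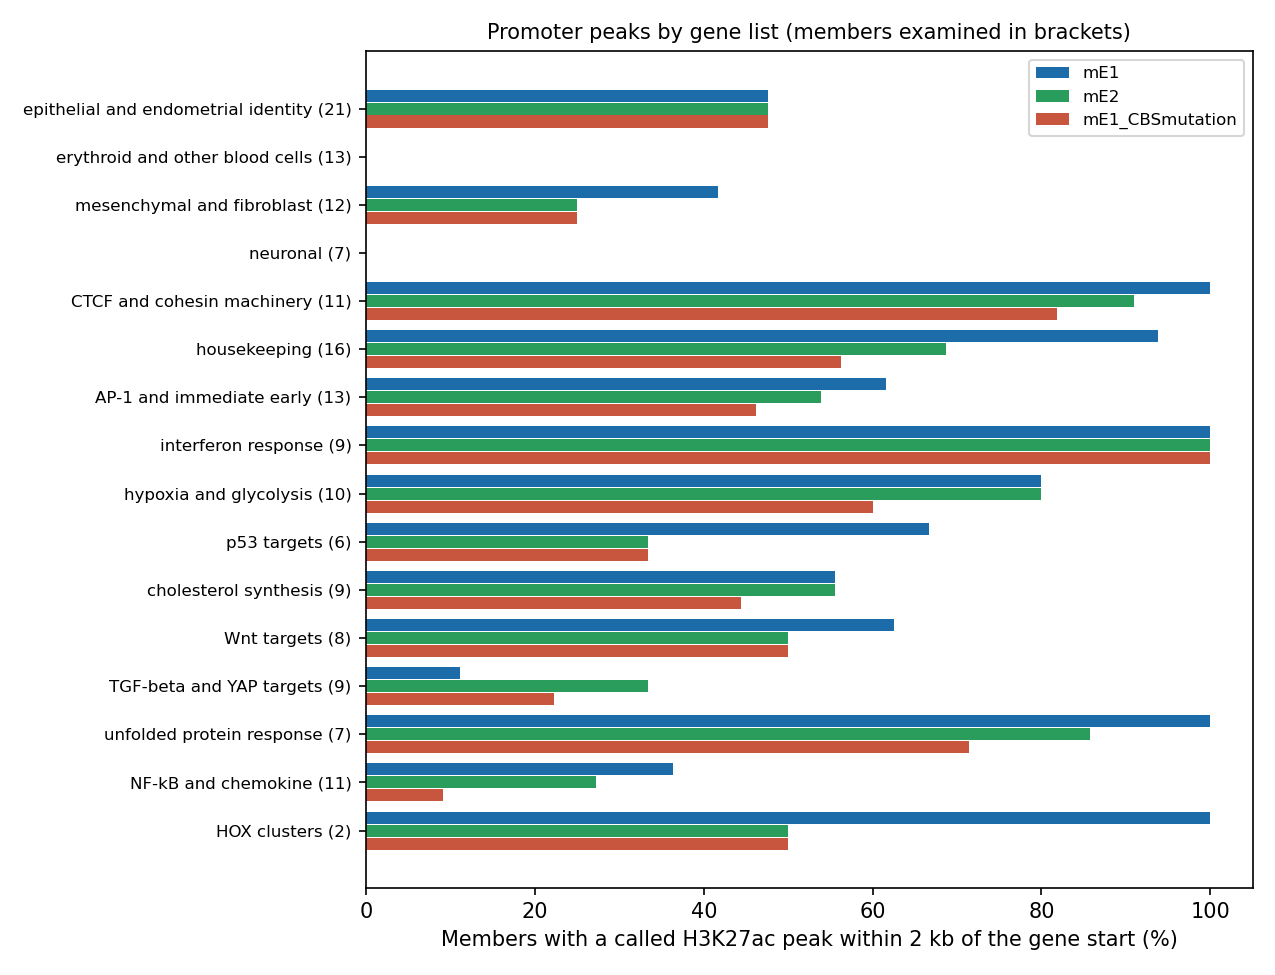
Members of each gene list with a called H3K27ac peak within 2 kb of the gene start (% of members examined, number in brackets), 1 bar per genotype, 1 library each and therefore no error bars. Blood cell and neuronal markers have none, and interferon response genes have a peak in every list. Of 16 housekeeping genes, 15 have a called peak in mE1, 11 in mE2 and 9 in mE1_CBSmutation.

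By chromosome, chromosome 3 held 8.25% of mE1 peaks (2421), 7.23% of mE2 peaks (2160) and 7.21% of mE1_CBSmutation peaks (1671). Among peaks above the median score, the mE1_CBSmutation share over the mE1 share was 0.985, and the mE2 share over the mE1 share was 0.931. Chromosome 6 held 4.81%, 5.86% and 5.42% of the lists, chromosome 4 held 3.02%, 3.45% and 3.42%, and chromosome X held 2.31%, 2.73% and 2.9%. Above the median score, the mE1_CBSmutation share over the mE1 share was 1.06 on chromosome 6, 1.16 on chromosome 4 and 1.28 on chromosome X, and the mE2 share over the mE1 share was 1.12, 1.23 and 1.48. Among 564 windows of 5 Mb, the largest excess of mE2 over mE1 lay at 185 to 190 Mb of chromosome 4, with 41 peaks in mE2, 16 in mE1 and 17 in mE1_CBSmutation. The largest deficit of mE1_CBSmutation against mE1 lay at 135 to 140 Mb of chromosome 3, with 30 peaks against 60 (ratio of shares 0.633). The next lowest ratio was 0.673, a deficit of under 1.5 times. The largest excess lay at 45 to 50 Mb of chromosome 14, with 13 peaks in mE1_CBSmutation against 8 (ratio 2.06). Shares of peaks differed by over 1.5 times in 9 windows between mE1 and mE1_CBSmutation, 20 between mE1 and mE2, and 13 between mE2 and mE1_CBSmutation. Of the 9, all but the chromosome 3 window were excesses of mE1_CBSmutation. With lists of equal length the counts for the 3 pairs were 13, 10 and 12, so their order changed, and with 2 Mb windows they were 42, 47 and 37.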

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

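The 2 alternatives that limit peak width were chosen after the data were seen. No paired analysis was possible because each genotype has 1 library, and for the same reason no library could be left out and no other split of the samples exists. Of the values that answer a comparison, 85 stayed within their interval or within 1.5 times the reported count and 57 moved. Of the other values, 192 stayed and 50 moved. For this purpose a Jaccard index was given the interval of a share of the peaks in both lists, as a yardstick only. Depth is unknown, so it limits every absence in an unmeasured way. Why an alternative moved a value was not tested, except where its construction gives the reason.

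With lists trimmed to equal length, the shares became 79.6% for mE1 peaks in mE1_CBSmutation and 79.6% in reverse, 79.8% for mE1 in mE2 and 79.6% in reverse, and 81.7% for mE2 in mE1_CBSmutation and 81.8% in reverse. Jaccard indices became 0.561 for mE1 with mE1_CBSmutation, 0.564 for mE1 with mE2 and 0.595 for mE2 with mE1_CBSmutation. In the lowest-scoring 10%, 44.9% of mE1 peaks had an mE1_CBSmutation partner and 39.1% in reverse, so the order of these 2 shares turned. Genes in mE1_CBSmutation and not mE2 rose in number to 6, and 13, 10 and 12 windows differed over 1.5 times between mE1 and mE1_CBSmutation, mE1 and mE2, and mE2 and mE1_CBSmutation.

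With reciprocal overlap of 50%, the shares were 63.5% and 80.4% for mE1 and mE1_CBSmutation in the order mE1 first, 70.7% and 69.4% for mE1 and mE2, and 63.9% and 82.4% for mE2 and mE1_CBSmutation. The lowest-scoring 10% of mE1 and mE1_CBSmutation gave 17.9% and 46.1%. Counting peaks within 1 kb as shared gave 70.3% for mE1 in mE1_CBSmutation, 28.8% in its lowest-scoring 10%, 79.8% for mE1 in mE2, 78.2% for mE2 in mE1 and 70.2% for mE2 in mE1_CBSmutation.

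With peaks above the median score, the lists held 14669, 14943 and 11586 peaks in mE1, mE2 and mE1_CBSmutation by construction. Shares were 80.2% for mE1 in mE2, 78.7% for mE2 in mE1, 88.3% for mE1_CBSmutation in mE1 and 89.9% for mE1_CBSmutation in mE2. The lowest-scoring 10% gave 30.9% for mE1 in mE1_CBSmutation and 64.7% in reverse. Jaccard indices were 0.544 for mE1 with mE1_CBSmutation and 0.554 for mE2 with mE1_CBSmutation. The protocadherin region then held 9 peaks in mE1, 5 in mE2 and 5 in mE1_CBSmutation, so the equal counts of mE1 and mE1_CBSmutation parted, 45 members of the gene lists had a promoter peak in mE1_CBSmutation, and 17 windows differed over 1.5 times between mE1 and mE1_CBSmutation.

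With peaks of 2 to 4 kb in the first list, shares were 86.0% for mE1 in mE1_CBSmutation, 93.3% in reverse, 91.2% for mE1 in mE2, 89.2% in reverse, 84.9% for mE2 in mE1_CBSmutation and 94.6% in reverse. With genes whose first-line peak was at most 4 kb wide, which by construction examines fewer genes, 13 had a peak in mE1 and not mE1_CBSmutation, 7 in mE1 and not mE2, 2 in mE2 and not mE1, and 4 in mE2 and not mE1_CBSmutation. The protocadherin region extended by 100 kb held 22, 21 and 22 peaks in mE1, mE2 and mE1_CBSmutation. Windows of 2 Mb, which hold fewer peaks each, differed over 1.5 times in 42 cases for mE1 and mE1_CBSmutation, 47 for mE1 and mE2, and 37 for mE2 and mE1_CBSmutation.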

Other observations

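Of the tests below, those on the missing peaks over 9 kb, on the reverse width trend and its excess, on the alpha promoters as a set and on the chromosome 3 share against mE2 were chosen after the results they bear on had been seen in part; the others were written before.

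Several promoters that are usually active in cultured cells had no called peak in any of the 3 lists. Examples, chosen after their values were seen, are MYC and JUNB, which encode growth-related transcription factors, CDKN1A, a p53 target, and SQLE of cholesterol synthesis. The epithelial genes CDH1, CLDN3, CLDN4, ESRP1 and GRHL2, and the endometrial genes ESR1, PGR and PAX8, also had none. Whether these are active in HEC-1-B cells was not examined. A start from background knowledge can be wrong for a single gene, the caller can miss a region, or acetylation can be lacking. Which of these holds was not tested, so each gene needs a look at the reads.

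High-scoring peaks, here those above the median score, lacked a partner more often over 6 kb than at 2 to 4 kb. Score above the median was not matched between these widths, so its part in the trend was not tested. Unpartnered peaks were still mostly 4 kb or narrower (71.9% for mE1 against mE1_CBSmutation). Most high-scoring peaks are that narrow, so this share does not weigh against the width trend. For the peaks over 6 kb a candidate explanation is that the caller missed wide enriched regions. Over the 3 lists the number of peaks fell steadily from 6293 at 4 to 5 kb to 2167 at 6 to 7 kb. Continuing that decline gives 1110 peaks over 9 kb, while 0 were listed. This comparison was set after the lists had been seen in part, so it does not test the explanation. Whether wide unpartnered peaks match regions missed in the other list was not examined. Loss of acetylation at wide domains through the CTCF-site mutation is argued against as the whole cause, since unpartnered peaks were also more frequent over 6 kb than at 2 to 4 kb for mE1_CBSmutation against mE1, by 8.39 percentage points, and for mE1 against mE2, by 11.4. An added loss stays open. The gap for mE1 against mE1_CBSmutation was 19.4 percentage points, an excess of 7.94 (3.07 to 12.8, peak sampling only) over mE1 against mE2. With 1 library per genotype and the shorter mE1_CBSmutation list, this excess cannot be placed. For mE2 the gap was likewise larger against mE1_CBSmutation (14.8) than against mE1 (7.33). At 2 to 4 kb, 4.95% of mE1 peaks lacked an mE1_CBSmutation partner and 3.43% an mE2 partner. The excess therefore depends on counting in percentage points. Regions coming out wider in the mE1_CBSmutation library also stay open (median width ratio to mE1 1.06, between the bounds set, against 1.04 for mE2 over mE1).

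The PCDHA6 peak was missing in mE1_CBSmutation and the PCDHAC1 peak in mE2. A general difference in calling between the libraries stays possible for both. Of mE1 peaks like the PCDHA6 peak, 9.56% lacked an mE1_CBSmutation partner, and 13.2% of those like the PCDHAC1 peak lacked an mE2 partner. These shares hold misses in calling and real differences together, so they cannot decide the cause. An effect of the CTCF-site mutation on PCDHA6 cannot be told apart from a difference in calling, because there is 1 library per genotype. The peak before PCDHAC1 was likewise called in mE1 and mE2 and missing in mE1_CBSmutation. Of the 4 alpha promoter peaks of mE1, 1 was missing in mE1_CBSmutation, a count that cannot decide the question. An effect of the HS5-1BL element on PCDHAC1, where 1 of the 4 was missing in mE2, is open as well.

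Chromosome 3 held a larger share of the mE1 list than of either other list, 1.14 times that of mE1_CBSmutation and 1.14 times that of mE2. Weak peaks near the calling threshold stay open as a cause. Above the median score the ratio was 1.02 to mE1_CBSmutation (0.927 to 1.12) and 1.07 to mE2 (0.977 to 1.17). Both intervals span the presence and the absence of an excess. They come from peak counts and take no account of shared peaks, so their width is uncertain. Above the median score, 80.2% of mE1 peaks overlapped mE2 and 69.8% overlapped mE1_CBSmutation. Of the 40 windows of 5 Mb on chromosome 3, 30 lay above the genome-wide ratio of mE1 to mE1_CBSmutation and 33 above that of mE1 to mE2. The mE1 list is the shared reference of both ratios, so a feature of that library alone could give both. These window counts do not test dosage, because the chromosome was picked for its excess, and no explanation tied to the genotypes was tested.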
